A study of Mus musculus with 20 samples.

How the data were processed

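RNA was extracted from cultures of mouse cerebellar granule neurons with the RNAqueous Micro Kit and made into 20 sequenced libraries, 5 in each of 4 groups, per the labels' protocols. The expression values are estimated counts of reads per gene, deposited as 1 table for the series, with 1 column per library and 1 entry per gene symbol. The name of the table gives salmon, a tool that estimates counts from reads mapped to transcripts, and calls the values merged gene counts. The genome build was mm10, per the submitters' processing notes. The version of salmon, the transcript annotation, trimming and filters are not given in the sources used here. The values were neither scaled to library size nor to transcript length: column totals differed between libraries, from 14200745 to 21179300, and 7.03 to 11.2% of the values in a library were not whole numbers. No pair of columns was identical, and any pair of libraries of a group differed by 29.3 to 418 times the sampling noise (chi-square per degree of freedom), so each library was kept as a sample. Each column was assigned to its sample by name, and no column was left over.

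Counts were rounded to whole numbers, as edgeR and DESeq2 need. Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 15284 of 24411 genes and removed 9127. Libraries were scaled with TMM factors, dispersions estimated over all 20 libraries, and groups compared with edgeR's quasi-likelihood test (robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library sizes and are given as means ± SD over 5 libraries. The 6 comparisons were each pair of the 4 groups, tested as contrasts of 1 fit.

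The group labels share the replicate numbers 1 to 5. Before calls were compared, the number was checked as a pairing. All 30 same-numbered pairs of libraries deviated together from their group means (Pearson r across genes 0.361 to 0.881, median 0.608). The 120 differently numbered pairs had a median of -0.205 and a highest value of 0.572. Deviations from a group mean sum to 0, so positive same-numbered values go with negative ones elsewhere. Of 20 libraries, 20 correlated best with a library of their own number. The labels do not say what a number stands for; the pairing comes from this check, with its limit of 0.1 for every pair. The design fixed before the data were examined had no replicate block. A fit with the number as an additive block was set down with it for comparison. Since the numbers pair the samples, its values are given as the paired fit, with counts of calls without pairing beside them. In shKdm6b against control the block raised the count of called genes from 1 to 632. The biological coefficient of variation fell from 0.392 to 0.179 with the block, and residual degrees of freedom from 16 to 12.

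Genes were named by a rule fixed in advance: the 10 largest rises and 10 largest falls (5 each for a rescue against control) among genes past the threshold, with a mean of at least 5 CPM over all libraries and groups that do not overlap, leaving out predicted and clone-named genes, plus Kdm6b, Kdm6a and up to 4 members of each list. Without pairing this rule named Camk2a alone. Applied to the paired calls, with all 5 same-numbered pairs changed the same way in place of groups that do not overlap, it was chosen after seeing the data. Some genes that the rule gives are not listed here. In total 29 lists of genes, with a joint list of synaptic genes, were fixed in advance and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. The lists were not drawn from this study. Of all list results with pairing that camera called, the interferon list between the active and dead rescue was the single one that also passed with an estimated correlation. Fry asks whether the genes of a list move, on balance, one way. Single values were compared with exact two-sided permutation tests, whose smallest p with 5 against 5 libraries is 0.00794, and exact sign-flip tests of the 5 pairs, whose smallest p is 0.0625. The log2 CPM used a prior count of 1.

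Simulated counts tested the fits for shKdm6b against control on 15284 genes, with 200 genes changed by known amounts. The changed genes were picked from those with an average log2 CPM above 2, so the shares recovered do not cover genes of lower counts. The counts were drawn from the gene means, dispersions, library sizes and replicate-number effects of the paired fit, which favours that fit. The fit without pairing recovered 5.97% of 1.5-fold, 32.8% of 2-fold and 86.4% of 4-fold changes; the paired fit recovered 53.7%, 89.6% and 98.5%, with 4 false calls among 165. Values of comparisons that share libraries were set against 20 simulations in which both rescues equal shKdm6b or, for comparisons with control, equal control. These simulations drew each gene separately and held no differences between replicate numbers in the effect of a group. Their ranges can therefore be too narrow for sets whose genes move together. Simulated sets took the observed number of genes by smallest p, a choice made after seeing the data, as were splits in which genes were chosen with 3 replicate numbers and measured with the other 2. Other alternatives were RLE and upper-quartile scaling, 2 other low-count filters, limma-voom, DESeq2 1.42.0, stricter thresholds, a fit of only the groups compared, each library left out in turn, and other splits of the samples (30 drawn of 126 possible, and all 16 that keep the pairs; fewer were drawn than first intended, to limit computing time). Alternatives chosen after seeing the data left out the libraries numbered 4, or kept only those numbered 1 to 3 or 4 and 5. Set tests at an estimated correlation where libraries were left out, and simulated rescues equal to shKdm6b with the shKdm6b libraries divided, were also chosen after seeing the data. So were simulated overlaps of sets of the observed sizes, and differences over the pairs left when a replicate number is left out. Gene positions come from a GENCODE annotation of GRCm38, in which 23983 of the table's genes (98.2%) matched by symbol, 649 of them through an older symbol. The mitochondrial genes of the RNA quality list have no entry in the table. The sequence of the shRNA and of the human domain was not used here.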

Results

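Gene expression was measured by RNA sequencing in cultures of mouse cerebellar granule neurons, the small excitatory neurons that form the granule layer of the cerebellum. Kdm6b encodes a histone demethylase that removes the repressive methyl marks from lysine 27 of histone H3. The 4 groups were control, an shRNA against mouse Kdm6b, the same shRNA with an active human KDM6B enzymatic domain, and the same shRNA with an enzymatically dead form of that domain. Cultures were infected on day 1 in vitro, treated with the antimitotic AraC on day 2 and harvested on day 7. What the control cultures were infected with is not stated by the labels. Each group held 5 libraries, numbered 1 to 5. The labels do not say that the libraries came from separate cultures or animals, so p-values measure the spread between these samples. Total estimated counts per library ran from 14200745 to 21179300, and 16874 to 17355 genes were detected per library. Of 24411 genes in the table, 15284 passed the expression filter and were tested.

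Libraries with the same number resembled each other across groups. Libraries numbered 1 to 3 held 2.43 to 7.24% of their counts in Rn45s, the ribosomal RNA precursor, against 0.206 to 0.611% in those numbered 4 and 5, and the nuclear long noncoding RNA Malat1 stood at 4422 to 6888 CPM against 217 to 997 CPM. Libraries numbered 4 stood apart on the first principal component, which held 40.5% of the variance. In these 4 libraries Apoe, an astrocyte and microglia gene, reached 3199 to 7627 CPM, and the X-linked paralogue Kdm6a stood at 11.3 to 33.1 CPM. Libraries numbered 5 carried the most Col3a1, a fibroblast collagen, at 6754 to 9111 CPM.

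Kdm6b was reduced in the shRNA cultures. Its level was 144 ± 40.5 CPM (SD, n = 5) in control and 83.0 ± 28.3 CPM (n = 5) in shKdm6b, a mean log2 difference of -0.83, or 56.3% of control, and it was lower in 5 of 5 same-numbered pairs. The difference exceeded the spread between libraries in an exact two-sided permutation test (p = 0.0317; Benjamini-Hochberg adjusted over the 6 group pairs, 0.19). The exact sign-flip test of the 5 pairs gave p = 0.0625, the smallest it can give. In the paired edgeR fit the log2 fold change was -0.88 ± 0.21 (SE; adjusted p = 0.0231), and without pairing -0.79 ± 0.43 (adjusted p = 1). The permutation p rose above the threshold, to between 0.0556 and 0.0794, when control 1, 2, 3 or 5 or shKdm6b 4 or 5 was left out, and the log2 difference ranged from -1.05 without control 4 to -0.59 without shKdm6b 4. In the paired fit the call ended without control 4 or 5 or shKdm6b 1, 3 or 5, with an adjusted p of up to 0.0937 without control 5. The gene lies on chromosome 11, from 69398508 to 69413675 on the minus strand (GENCODE annotation of GRCm38, the assembly also called mm10, with coordinates of the whole gene including its exons, introns and UTRs; that annotation may differ from the one used for counting).

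Kdm6b reads were higher than in shKdm6b in both rescue groups, at 212 ± 109 CPM (n = 5) with the active domain and 176 ± 92.2 CPM (n = 5) with the dead domain. Both exceeded shKdm6b in 5 of 5 pairs, by 1.24 and 0.95 on the log2 scale, but neither difference passed the exact permutation test (p = 0.0635 and 0.103) or edgeR's adjusted threshold in the paired fit (0.0865 and 1). Reads of the human domain may have been counted under the mouse gene, so the endogenous level in the rescue groups is not measured here. Libraries numbered 1 to 3 of both rescues held 192 to 312 CPM, above the 139 to 171 CPM of their controls. Those numbered 4 held 73.2 (active) and 54.9 (dead) against 81.2 CPM in control, and those numbered 5 held 119 and 109 against 187 CPM. The active group lay above the dead group in 5 of 5 pairs, by 0.28 ± 0.17 (SD; exact sign-flip p = 0.0625, the smallest possible; exact permutation p = 0.611). Kdm6a stood at 48.1 ± 22.6 CPM in control and 44.4 ± 19.9 CPM in shKdm6b (n = 5 each), a difference smaller than the spread between libraries (exact permutation p = 0.794).

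**Figure D1:**
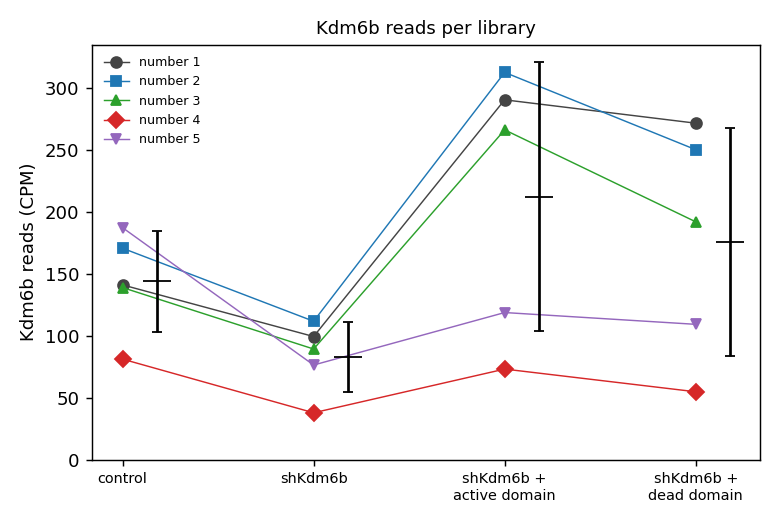
Kdm6b reads in CPM (vertical axis) in each of the 4 groups (horizontal axis), with 1 point per library, lines joining libraries of the same number, and black bars for the mean and SD of 5 libraries. All 5 shKdm6b libraries lie below the same-numbered control, with means of 83.0 and 144 CPM.

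The comparison of shKdm6b with control asked which genes depend on Kdm6b in these neurons. The genes that rose most in shKdm6b included several that were almost silent in control. Hoxd3, a homeobox transcription factor of body patterning, rose from 0.383 ± 0.469 to 17.6 ± 17.5 CPM (n = 5 each), a log2 fold change of 5.60 ± 0.34 (SE; edgeR paired adjusted p = 1.89e-07). Pitx1, a homeobox factor of hindlimb and pituitary, rose from 0.362 ± 0.593 to 14.6 ± 17.9 CPM (5.35 ± 0.42). Hoxd3 overlaps Hoxd4 on chromosome 2, so its reads cannot be assigned to it with certainty. The galanin receptor gene Galr1 rose by 2.36 ± 0.46, Camk2a, the alpha subunit of the calcium/calmodulin-dependent kinase of excitatory synapses, by 2.25 ± 0.22, from 3.89 ± 1.41 to 18.1 ± 5.22 CPM, and Arhgap36 by 2.03 ± 0.26. Islr2, a membrane protein of growing axons, rose by 1.72 ± 0.28, the RNA-binding protein gene Celf6 by 1.61 ± 0.16, the long noncoding RNA Miat by 1.59 ± 0.19 and the netrin receptor gene Unc5d by 1.57 ± 0.28. In the paired edgeR fit these 9 genes had adjusted p-values up to 0.00659, for Galr1, and all 9 kept their calls when any 1 library was left out.

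Tnr led the 10 named genes with the largest falls in shKdm6b. This gene, which encodes the extracellular matrix protein tenascin-R, fell from 59.2 ± 37.2 to 11.7 ± 6.85 CPM, a log2 fold change of -2.24 ± 0.38 (edgeR paired adjusted p = 0.00286). The transporter-like gene Mfsd4 changed by -1.80 ± 0.29, and a pair of potassium channel genes fell beside it: Kcnip2, an accessory subunit of A-type channels, by -1.76 ± 0.23 and Kcnk12, a background channel, by -1.71 ± 0.33, from 88.5 ± 36.0 to 34.0 ± 20.1 CPM. Ntng1, the axonal adhesion protein netrin-G1, changed by -1.60 ± 0.32, and Gabrd, the delta subunit of extrasynaptic GABA-A receptors of mature granule neurons, by -1.59 ± 0.41, from 67.1 ± 14.7 to 29.0 ± 13.8 CPM. Further falls were those of Vipr1, a receptor of vasoactive intestinal peptide (-1.57 ± 0.35), Olfm3 (-1.48 ± 0.29), Grin2c, the NMDA receptor subunit of mature granule neurons (-1.47 ± 0.28), and Prmt8, a neuronal arginine methyltransferase (-1.46 ± 0.19). Of these 10 genes, Gabrd lost its call without control 5 or any 1 of the 5 shKdm6b libraries (adjusted p up to 0.111, without shKdm6b 5). Its log2 fold change was -0.94 without control 4. Vipr1 lost its call without shKdm6b 1 or 5 (adjusted p up to 0.0649).

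In all, 632 of 15284 genes passed an adjusted p of 0.05 in the paired edgeR fit, 263 higher and 369 lower in shKdm6b, and 378 of them changed at least 1.5-fold. The fit without pairing called 1 gene, Camk2a (log2 fold change 2.21, adjusted p = 0.0157; 0 genes without control 1, 3 or 5 or shKdm6b 1 or 2, 9 without control 4, 3 without shKdm6b 3 and 8 without shKdm6b 4), with 477 genes under an unadjusted p of 0.05 where 764 would be under it by chance. DESeq2 called 62 genes without pairing and 1040 with it. The paired count was 414 without shKdm6b 1 and 352 without shKdm6b 5, of which 399 and 351 were among the 632, and 990 when the 4 libraries numbered 4 were left out. Libraries numbered 4 and 5 alone gave 0 calls in the paired edgeR fit.

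**Figure D2:**
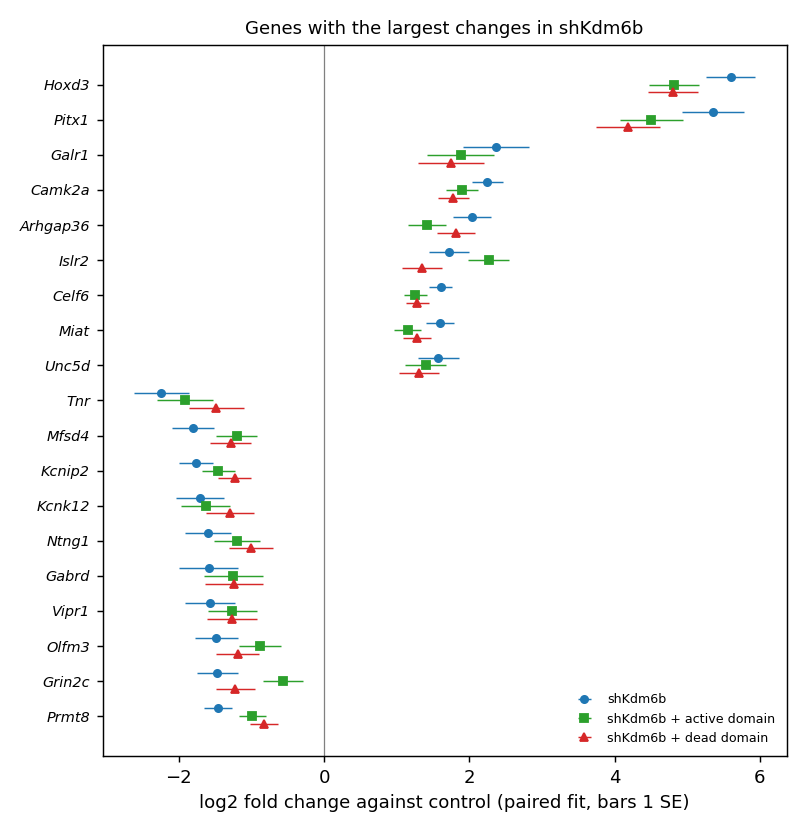
Log2 fold change against control (horizontal axis) of 9 of the 10 genes with the largest rise and the 10 with the largest fall in shKdm6b, in shKdm6b (circles) and in the active-domain (squares) and dead-domain (triangles) rescues, from the paired fit with bars of 1 SE. Hoxd3 lies at 5.60, 4.82 and 4.81 and Kcnip2 at -1.76, -1.45 and -1.23, so both rescue groups lie on the same side of control as shKdm6b.

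Fixed gene lists were tested as groups with camera in limma, at its preset correlation between genes and adjusted over the lists of a comparison. Genes of late granule neuron maturation fell in shKdm6b: 12 of 33 measured members fell, 2 rose and 19 did not pass, with 15 lower and 2 higher adjusted over the list alone, a median log2 fold change of -0.30 and camera adjusted p = 5.01e-07 (adjusted p = 0.196 with an estimated correlation, fry 0.0244). Among them Cbln3, a cerebellin secreted by granule neurons, changed by -0.77 ± 0.13 (SE) and Etv1, a transcription factor of granule neuron maturation, by -1.02 ± 0.18. Pcp4, a calmodulin-binding peptide best known from Purkinje cells, moved the other way, by 1.28 ± 0.18. The early granule neuron and progenitor list rose (4 of 34 higher, 2 lower, 28 not passing; 8 higher and 4 lower adjusted over the list alone; median 0.12, camera adjusted p = 0.0186, adjusted p = 0.652 with an estimated correlation), with Barhl1, a homeobox factor of granule neuron precursors, at 0.98 ± 0.13 and the neuronal tubulin Tubb3 at 0.64 ± 0.10. The cell cycle list fell (0 higher, 1 lower, 35 not passing, the same adjusted over the list alone; median -0.15, adjusted p = 0.000373, and adjusted p = 0.646 with an estimated correlation), and the single member called was Rrm2, a ribonucleotide reductase subunit (-1.06 ± 0.15). Markers of granule neurons themselves did not pass (2 higher, 3 lower, 9 not passing of 14; 2 higher and 5 lower adjusted over the list alone; median -0.17, camera adjusted p = 0.0780). Without pairing the late maturation, early granule and cell cycle lists had camera adjusted p-values of 0.00219, 0.00232 and 0.0127.

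Synaptic genes moved in both directions. Presynaptic vesicle and release genes fell as a list (8 lower, 1 higher and 40 not passing of 49; 13 lower and 3 higher adjusted over the list alone; median -0.14, camera adjusted p = 0.000179, adjusted p = 0.646 with an estimated correlation). Nrxn3, a presynaptic adhesion protein, changed by -0.66 ± 0.10 (SE) and the vesicle fusion factor Napb by -1.10 ± 0.20, while the release machinery gene Stx1a rose by 1.04 ± 0.15. The list of voltage-gated ion channels fell (5 lower, 1 higher, 37 not passing of 43, median -0.18). Adjusted over the list alone, 8 were lower and 1 higher (camera adjusted p = 0.00181, adjusted p = 0.646 with an estimated correlation). The list also holds some inward rectifier and background potassium channels, which are not voltage-gated. The inward rectifier gene Kcnj3 changed by -0.81 ± 0.15, while the voltage-gated potassium channel gene Kcnc4 rose by 1.33 ± 0.18. Glutamate receptors and postsynaptic scaffold genes did not pass as a list (6 lower, 3 higher, 39 not passing of 48, camera adjusted p = 0.411). Adjusted over the list alone, 8 were lower and 3 higher. Dlgap1, a scaffold of the postsynaptic density, fell by 0.82. Neto1, an accessory protein of kainate receptors, rose by 2.82, from 0.927 ± 0.249 to 8.22 ± 5.90 CPM. It was not higher in the pair numbered 3 (1.13 CPM in shKdm6b, 1.18 CPM in control). GABA and glycine receptors did not pass either (1 lower, 1 higher, 16 not passing; 3 and 3 adjusted over the list alone; adjusted p = 0.513). All synaptic lists together held 15 lower and 5 higher of 115 genes (22 lower and 8 higher adjusted over the list alone; camera adjusted p = 0.00257, and adjusted p = 0.451 with an estimated correlation). With the 4 libraries numbered 4 left out, the presynaptic, channel and joint synaptic lists no longer passed (camera adjusted p = 0.0622, 0.0680 and 0.230). Late maturation still passed at the preset correlation (1.48e-05), though not with an estimated correlation (adjusted p = 0.443). None of the presynaptic, channel and joint synaptic lists passed camera without pairing.

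Interferon and antiviral genes rose together in shKdm6b. All 46 members had a positive log2 fold change, with a median of 0.32; 7 passed over all genes and 13 adjusted over the list alone, none lower (camera adjusted p = 1.06e-14 paired and 1.90e-11 without pairing, adjusted p = 0.196 with an estimated correlation, fry 0.0244). Ifit3 and Ifit3b, interferon-induced proteins that share similar sequence, rose by 0.63 ± 0.12 and 0.65 ± 0.13 (SE), and reads that fit both copies could have been split between them. Per library, the mean log2 level of the list was 0.38 ± 0.20 higher (SD over 5 pairs, 5 of 5 higher; exact sign-flip p = 0.0625, the smallest possible; exact permutation p = 0.23). Microglia and macrophage markers were lower as a list with all libraries (median -0.33, 0 of 18 positive, 1 called lower, the same adjusted over the list alone; camera adjusted p = 0.00692, adjusted p = 0.684 with an estimated correlation). Per library their mean was lower in 3 and higher in 2 of 5 pairs (-0.30 ± 0.66, SD; exact sign-flip p = 0.5). The camera call ended without the libraries numbered 4 (0.567) and its direction turned with numbers 1 to 3 alone (0.614). NF-kB and inflammatory genes did not pass (1 of 31 higher, the chemokine gene Cxcl10, and the same adjusted over the list alone; camera adjusted p = 0.170).

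Hox genes and other developmental regulators silenced by Polycomb complexes rose as a list, with 2 of 47 measured members higher, none lower and 45 not passing, the same adjusted over the list alone (median 0.06, camera adjusted p = 0.0150, adjusted p = 0.196 with an estimated correlation, and 0.103 without the libraries numbered 4; the list did not pass without pairing). The members called were Hoxd3 and Pax2, a paired-box factor of cerebellar interneuron precursors (1.05 ± 0.22, SE). Activity-regulated genes fell (4 lower, 0 higher, 28 not passing; 11 lower and 2 higher adjusted over the list alone; median -0.21, camera adjusted p = 0.00269, adjusted p = 0.196 with an estimated correlation), among them Nptx1, a secreted pentraxin of synapses (-0.81 ± 0.15), and the immediate-early transcription factor gene Nr4a1 (-0.93 ± 0.19). Cholesterol biosynthesis genes fell (1 lower, 24 not passing; 2 lower adjusted over the list alone; median -0.14, camera adjusted p = 0.00127, adjusted p = 0.314 with an estimated correlation, and 0.307 with numbers 1 to 3 alone; per library lower in 3 of 5 pairs, exact sign-flip p = 0.25), the called member being Insig1, a sterol-regulated retention protein (-0.36 ± 0.07). Of 45 autism-associated genes 4 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.0730), including Kdm6b itself and the scaffold gene Shank3 (-0.68 ± 0.13). Axon guidance and cell adhesion genes went both ways (3 higher, 4 lower, 51 not passing; 4 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.105), with the ephrin gene Efnb3 raised by 1.11 ± 0.15.

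The remaining lists did not pass camera in shKdm6b against control. The other enzymes that write or remove H3K27 methylation held 1 lower call, Kdm6b itself (2 lower adjusted over the list alone; adjusted p = 0.105), and the COMPASS complex and the other JmjC demethylases held 0 calls in edgeR, also adjusted over the list alone (camera in limma, adjusted p = 0.648 and 0.327; smallest unadjusted member p in edgeR = 0.0318 for Pagr1a and 0.0677 for Phf8). The p53 and apoptosis list and nuclear-encoded oxidative phosphorylation genes likewise held 0 calls over all genes or adjusted over the list alone (camera adjusted p = 0.1002 and 0.0668). The integrated stress response list held 1 lower call, Aldh18a1, the same adjusted over the list alone (camera adjusted p = 0.215). Among cell type markers, camera adjusted p-values were 0.464 for astrocytes and Bergmann glia, 0.254 for the oligodendrocyte lineage, 0.105 for endothelial, mural and meningeal cells, 0.0559 for GABAergic interneurons and Purkinje cells, 0.197 for unipolar brush and nuclear neurons and 0.0730 for ciliated, choroid plexus and ependymal cells. Per library the unipolar brush and nuclear neuron markers were higher in 5 of 5 pairs (0.19 ± 0.09, exact permutation p = 0.0238), and lower in 5 of 5 pairs in the dead rescue against shKdm6b (-0.12 ± 0.07, exact permutation p = 0.0159). Neither p was adjusted over the lists, and 6 of the 9 measured markers stand in other lists too. In the cell type marker lists single genes still passed: Gad1, the GABA-synthesizing enzyme of interneurons, fell by 0.60 on the log2 scale. The mitochondrial transcripts meant to show RNA quality are absent from the table used here.

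The next comparison asked whether the active domain changed expression in cells that carried the shRNA. Kcnip1, a potassium channel-interacting protein, was the single gene called between the active rescue and shKdm6b in the paired edgeR fit, at 6.07 ± 4.71 against 1.48 ± 0.749 CPM (n = 5 each; log2 fold change 1.86 ± 0.24 SE, adjusted p = 0.0115, higher in 5 of 5 pairs). It lies outside the rule for named genes and was chosen after its values were seen. The call was lost in 5 of the 10 fits that left out 1 library (shKdm6b 1, 2 or 3 or active 1 or 2), and libraries 1 to 3 alone called 17 genes. Without pairing edgeR called 0 genes, with 50 under an unadjusted p of 0.05 and 764 expected by chance, against 577 in the paired fit; DESeq2 called 1 without and 197 with pairing. Interferon genes were lower (0 of 46 positive, median -0.30; 0 called over all genes and 15 lower adjusted over the list alone; camera adjusted p = 1.46e-39, adjusted p = 0.0502 with an estimated correlation, fry 0.107). Ifit3, for instance, stood at 123 ± 52.0 against 168 ± 74.9 CPM, and did not pass alone. Cell cycle genes were lower (camera adjusted p = 4.67e-08, median -0.13, adjusted p = 0.486 with an estimated correlation), and late maturation genes higher (5.71e-05, median 0.10, adjusted p = 0.431 with an estimated correlation), with 0 edgeR calls in either list, also adjusted over the list alone. Among cell type markers, those of the oligodendrocyte lineage were lower (median -0.22, camera adjusted p = 0.00225, adjusted p = 0.453 with an estimated correlation; 0.00777 without the libraries numbered 4; lower in 4 of 5 pairs) and those of ciliated and choroid plexus cells lower (median -0.11, 0.00780, adjusted p = 0.453 with an estimated correlation). Markers of GABAergic interneurons and Purkinje cells (median 0.15, 0.00477, adjusted p = 0.110 with an estimated correlation) and endothelial and mural cells (median 0.16, 0.00327, adjusted p = 0.431 with an estimated correlation) were higher. The calls of ciliated and choroid plexus (0.398), GABAergic and Purkinje (0.255) and endothelial and mural markers ended without the libraries numbered 4. These marker lists held 0 edgeR calls over all genes, and adjusted over the list alone 1, higher, among the endothelial and mural markers. All synaptic lists together were higher by a median of 0.08 (camera adjusted p = 2.83e-06, adjusted p = 0.251 with an estimated correlation), a call that ended and turned in direction without the libraries numbered 4 (0.680). Presynaptic Syt2 and the channel subunit gene Cacna2d2 stood at 1.05 ± 0.24 and 0.67 ± 0.16 (adjusted p = 0.454 for both).

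The dead domain gave a control for the enzyme. Against shKdm6b it called 0 genes in edgeR, paired or not, with 214 and 25 under an unadjusted p of 0.05 where 764 would be expected; DESeq2 called 0 without pairing and 145 with it. Kdm6b reads had the smallest p (log2 fold change 0.98 ± 0.21 SE, adjusted p = 1). The interferon list lay at the shKdm6b level (median 0.01, camera adjusted p = 0.514). Synaptic lists together were higher by a median of 0.04 (camera adjusted p = 0.00736, adjusted p = 0.504 with an estimated correlation), and lower once the libraries numbered 4 were left out (1.96e-05). Late maturation genes were higher by a median of 0.11 (camera adjusted p = 0.00183, adjusted p = 0.638 with an estimated correlation), a call that ended without the libraries numbered 4 (0.816). Granule neuron markers were higher as well (median 0.08, 0.0421, adjusted p = 0.922 with an estimated correlation), and lower without the libraries numbered 4 (0.0106). Markers of GABAergic interneurons and Purkinje cells were higher (median 0.04, 0.0410, adjusted p = 0.263 with an estimated correlation) and of ciliated and choroid plexus cells lower (median -0.17, 0.00227, adjusted p = 0.465 with an estimated correlation), both not without the libraries numbered 4 (0.404 and 0.453). These 3 lists held 0 edgeR calls, also adjusted over the list alone.

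Whether the enzymatic activity matters was asked by setting the active against the dead domain, which both carry the shRNA. Again Kcnip1 was the single gene called in the paired edgeR fit, at 6.07 ± 4.71 CPM with the active and 1.71 ± 0.957 CPM with the dead domain (n = 5 each; log2 fold change 1.67 ± 0.24 SE, adjusted p = 0.0411, higher in 5 of 5 pairs). That call held in 2 of the 10 fits that left out 1 library, those without active 4 or active 5, and the other 8 called no gene. Without pairing edgeR called 0 genes (37 under an unadjusted p of 0.05, 764 expected; 415 in the paired fit), and DESeq2 called 1, or 173 with pairing. Libraries 1 to 3 alone gave 9 calls in the paired edgeR fit, and 0 were called without the libraries numbered 4.

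Interferon and antiviral genes were lower with the active than with the dead domain, the list result with the smallest p in this comparison. Of 46 members 44 were lower, by a median log2 fold change of -0.34; 0 passed over all genes in edgeR and 20 were lower adjusted over the list alone (camera adjusted p = 1.19e-53 paired and 2.44e-29 without pairing, adjusted p = 0.0158 with an estimated correlation, fry 0.0733). Oas2, an antiviral enzyme that senses double-stranded RNA, stood at 36.8 ± 22.2 against 52.3 ± 25.4 CPM (n = 5; log2 fold change -0.56 ± 0.12 SE), the interferon regulator Irf7 at 138 ± 99.8 against 234 ± 142 CPM (-0.78 ± 0.20) and the ubiquitin-like Isg15 at 150 ± 83.8 against 230 ± 137 CPM (-0.60 ± 0.17). Per library the list mean was lower by a log2 difference of -0.37 ± 0.29 (SD over 5 pairs, 4 of 5 lower; exact sign-flip p = 0.125, exact permutation p = 0.317), so library means alone did not separate the groups. Against control, the list was at 0.39 ± 0.21 in the dead rescue (5 of 5 pairs higher; camera adjusted p = 1.81e-23, adjusted p = 0.268 with an estimated correlation) and at 0.02 ± 0.28 in the active rescue (3 of 5 higher). Microglia markers did not differ detectably between active and dead (median -0.05, camera adjusted p = 0.230).

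**Figure D3:**
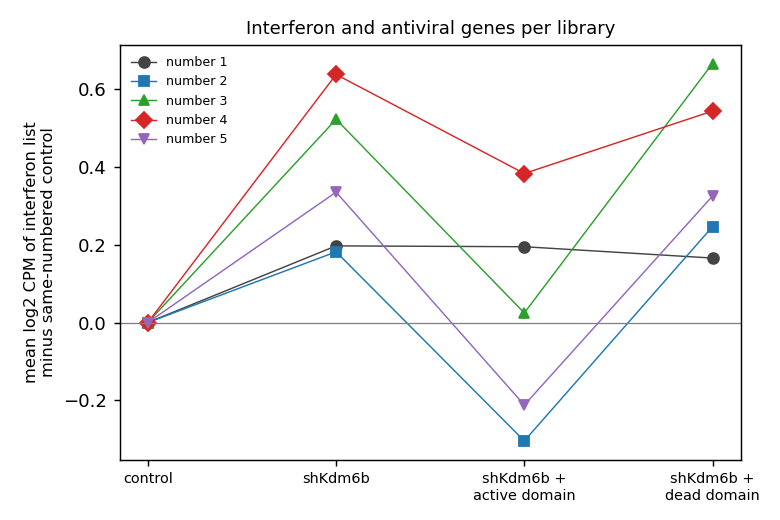
Mean log2 CPM of the 46 interferon and antiviral genes minus the same-numbered control library (vertical axis) in the 4 groups (horizontal axis), 1 point per library, with lines joining libraries of the same number. The shKdm6b and dead-domain libraries lie above control in 5 of 5 pairs, and the active-domain libraries in 3 of 5.

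Other lists moved less between active and dead. Cell cycle genes were lower with the active domain (34 of 36 members, median -0.17, camera adjusted p = 1.21e-11, adjusted p = 0.554 with an estimated correlation; per library -0.19 ± 0.40, lower in 3 and higher in 2 of 5 pairs, exact sign-flip p = 0.375), and axon guidance genes higher (51 of 58, median 0.14, adjusted p = 5.07e-07, adjusted p = 0.827 with an estimated correlation). Glutamate receptors and postsynaptic scaffold genes were higher by a median of 0.07 and voltage-gated channels by 0.08 (adjusted p = 0.00491 for both, adjusted p = 0.827 with an estimated correlation for both). All synaptic lists together were higher by a median of 0.04 in 82 of 115 genes (camera adjusted p = 0.00448, adjusted p = 0.480 with an estimated correlation). None of these members passed over all genes in edgeR or adjusted over the list alone. Oxidative phosphorylation genes (median -0.09, 0.00134), endothelial and mural markers (median 0.10, 0.00491) and JmjC demethylases (median 0.10, 0.0473) passed camera with all libraries and not without the libraries numbered 4 (0.757, 0.413 and 0.238), nor with an estimated correlation (adjusted p = 0.871, 0.554 and 0.827).

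Genes changed by the knockdown were then followed in the rescues. The set planned from the fit without pairing held 1 gene, Camk2a, and none lower; the paired calls gave 263 higher and 369 lower genes. Between the active and dead domain the higher set differed by a median log2 fold change of 0.02 (camera p = 0.415, fry 0.714, exact permutation of library means p = 0.817) and the lower set by 0.003 (camera p = 0.865, exact permutation p = 0.968). The higher set was higher with the active domain when the 4 libraries numbered 4 were left out (7.18e-10 by camera on the edgeR paired fit, 0.0964 with an estimated correlation). It was also higher without shKdm6b 4 (0.00170, 0.436 with an estimated correlation) or without dead 4 (1.70e-07, 0.111 with an estimated correlation). The lower set passed camera without active 1 (0.0329), dead 1 (0.00483), dead 2 (0.0242) or dead 3 (0.0271), and without active 1 or dead 1 its camera direction turned. With an estimated correlation these 4 were 0.510, 0.368, 0.511 and 0.524.

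Against shKdm6b, the lower set lay at a median of 0.15 with the active and 0.16 with the dead domain, and the higher set at -0.13 and -0.14. The sets were chosen with the same shKdm6b libraries. In sets of the same sizes, simulated rescues equal to shKdm6b gave 0.06 (0.04 to 0.08) and 0.06 (0.05 to 0.08) for the lower and -0.08 (-0.10 to -0.05) and -0.08 (-0.10 to -0.07) for the higher set (20 simulations). The share of genes on the opposite side of shKdm6b was 93.5 and 97.3% in the lower set, beside a simulated 65.6% for both, and 84.0 and 93.5% in the higher set, beside 68.8 and 69.4%. The simulated counts held more called genes than the real ones (medians of 524 higher and 640 lower). With genes chosen on 3 shKdm6b libraries and measured on the other 2, in 10 splits, the lower set lay at 0.15 (0.03 to 0.21) with the active and 0.16 (-0.09 to 0.31) with the dead domain, above 0 in 10 and 9 splits. The higher set lay at -0.06 (-0.34 to 0.14) and -0.12 (-0.50 to 0.15), above 0 in 5 of 10 splits with either domain. Splits chosen after seeing the data, with no replicate number in both steps, gave 0.15 (0.07 to 0.25) and 0.12 (-0.03 to 0.30) for the lower set, above 0 in 10 and 9 of 10. For the higher set they gave -0.08 (-0.20 to 0.15) and -0.12 (-0.34 to 0.15), above 0 in 4 of 10 with either domain.

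Against control, the higher set lay at 0.60 with the active and 0.55 with the dead domain, beside 0.70 in shKdm6b, and the lower set at -0.43 and -0.45, beside -0.62. These values share the control libraries that chose the sets, and simulated rescues equal to control gave 0.09 and 0.09 for the higher and -0.06 and -0.06 for the lower set. Simulated rescues equal to shKdm6b gave 0.75 (0.70 to 0.81) and 0.74 (0.69 to 0.78) for the higher and -0.65 (-0.68 to -0.61) and -0.66 (-0.68 to -0.62) for the lower set. Genes were again drawn separately, so these ranges can be too narrow. In the splits with no replicate number in both steps the higher set lay at 0.53 (0.42 to 0.64) with the active, 0.45 (0.35 to 0.67) with the dead domain and 0.58 (0.48 to 0.65) in shKdm6b. The lower set lay at -0.38 (-0.42 to -0.35), -0.41 (-0.51 to -0.32) and -0.54 (-0.67 to -0.43).

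**Figure D4:**
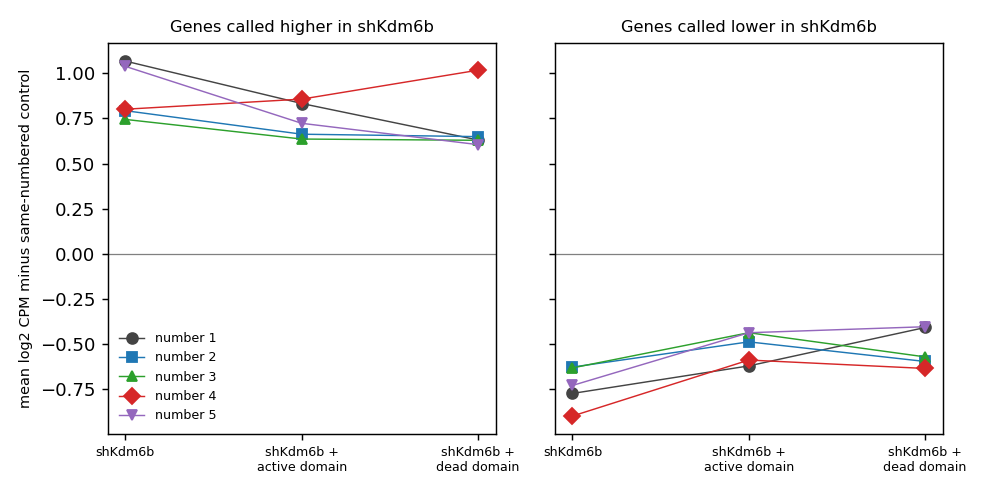
Mean log2 CPM of the 263 genes called higher (left) and the 369 called lower (right) in shKdm6b, minus the same-numbered control library (vertical axis), in the 3 groups that carry the shRNA (horizontal axis), 1 point per library. Every library of both rescue groups lies on the same side of control as shKdm6b.

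The rescues were also set against control. In the paired edgeR fit 299 genes differed with the active domain, 166 higher and 133 lower, and 181 with the dead domain, 88 higher and 93 lower; without pairing both gave 0 (387 and 276 under an unadjusted p of 0.05, 764 expected; DESeq2 called 23 and 18). Among called genes with a mean of at least 5 CPM Hoxd3 and Pitx1 rose most in both (with the dead domain Tmem211, below that level, stood at 4.86 ± 0.63), at log2 fold changes of 4.82 ± 0.34 (SE) and 4.50 ± 0.43 with the active and 4.81 ± 0.34 and 4.18 ± 0.43 with the dead domain. Islr2 stood at 2.27 ± 0.28 with the active domain and Arhgap36 at 1.81 ± 0.26 with the dead domain, and Neto1 at 2.30 ± 0.43 and 2.13 ± 0.44. Lower genes with the active domain were Kcnk12 (-1.63 ± 0.33), Kcnip2 (-1.45 ± 0.23), Ramp3, a partner of calcitonin-family receptors (-1.43 ± 0.25), Crabp2, a retinoic acid-binding protein (-1.26 ± 0.24), and Xk (-1.25 ± 0.18). With the dead domain they were Mfsd4 (-1.29 ± 0.28), Kcnip2 (-1.23 ± 0.22), Grin2c (-1.22 ± 0.27), Xk (-1.04 ± 0.17) and Ankrd34a (-0.97 ± 0.20). Kcnk12 lost its call without active 1 (adjusted p = 0.0677), and with the dead domain Kcnip2 lost its call without dead 2 (0.0527), Ankrd34a in 4 of 10 leave-one-out fits, Neto1 and Mfsd4 in 7 and Grin2c in 9 (up to 0.0970, 0.0922, 0.140 and 0.143).

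Most of these calls had the direction of the knockdown. Of the genes higher with the active domain 125 of 166 were also higher in shKdm6b, and of those lower 126 of 133; for the dead domain the numbers were 86 of 88 and 91 of 93. Independent lists of these sizes would share 2.86, 3.21, 1.51 and 2.25 genes. The 3 comparisons use the same control libraries. Sets of the same sizes, taken by smallest p from simulated rescues equal to control, shared a median of 14 (6 to 23), 13 (8 to 20), 9.50 (5 to 12) and 11 (5 to 15) genes over 20 simulations. From simulated rescues equal to shKdm6b they shared 133 (121 to 141), 125 (120 to 129), 82.5 (78 to 88) and 91 (88 to 93). Both simulations drew genes separately, so their ranges can be too narrow. The active count fell to 128 without active 1 and to 149, 190 and 175 without control 1, control 2 and active 2. The dead count was 67 without control 1, 101 without control 2, 119 without control 4, 106 without control 5, 65, 67 and 66 without dead 2, 3 and 4, and 113 without dead 5. Without the 4 libraries numbered 4 the counts were 700 and 378. Against control the late maturation list was lower in both rescues (camera adjusted p = 0.00924 active and 0.000104 dead; adjusted p = 0.714 and 0.443 with an estimated correlation).

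The effects of both domains were compared across genes. Log2 fold changes against shKdm6b correlated between the active and dead domain (Pearson r = 0.574 over 15284 genes, which are not independent replicates), but both use the same shKdm6b libraries. Simulated unchanged groups gave r = 0.495 (0.354 to 0.541), and the observed covariance, 0.0317, lay beside a simulated 0.0322. With the shKdm6b libraries divided between both contrasts, in 20 splits, r had a median of -0.0518 (-0.339 to 0.0688), and simulated rescues equal to shKdm6b gave a median of 0.00111 (-0.0257 to 0.0240). The simulation holds no differences between replicate numbers in the effect of a group, so this r does not show whether the effects were alike.

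The main genes lie as follows in the same annotation. Camk2a spans 60925618 to 60988152 on chromosome 18, Hoxd3 74711927 to 74748442 on chromosome 2 and Pitx1 55825051 to 55836192 on chromosome 13. Tnr spans 159523769 to 159931729 on chromosome 1, Kcnip2 45791839 to 45816061 on chromosome 19, Gabrd 155384980 to 155398112 on chromosome 4 and Grin2c 115249169 to 115267243 on chromosome 11. Each is annotated as protein-coding; Miat, on chromosome 5 from 112213228 to 112229395, is annotated as a long intergenic noncoding RNA.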

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

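The comparison of the active with the dead domain and the search for distant libraries were planned, and all tests of explanations here, with their limits, were chosen after the result was seen. Among 128 groups of 5 libraries searched for a library far from the other 4, 22 held one, where chance would give about 5%, and 18 of the 22 were libraries numbered 4. In control 4, Tnr stood at 1.36 CPM against 49.1 to 95.5 in the other controls, Xk at 4.49 and Kdm6a at 11.3 CPM. In shKdm6b 4, Tnr stood at 0.230, Mfsd4 at 0.782, Gabrd at 5.34, Olfm3 at 2.90, Xk at 1.66, Galr1 at 3.82 and Kdm6a at 12.5 CPM. That library also had the lowest mean log2 CPM of its group for late maturation genes (4.87) and for granule neuron markers (6.49). In active 4, Kcnk12 stood at 2.59, Gabrd at 3.32, Olfm3 at 4.44 and Grin2c at 4.74 CPM, and the late maturation mean at 5.38. In dead 4, Gabrd stood at 7.53 CPM. The distant libraries outside number 4 were active 5 and dead 5 for Camk2a (8.98 and 5.38 CPM), control 3 for Ramp3 (13.5 CPM) and shKdm6b 5 for Kcnip1 (0.242 CPM).

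Kcnip1 and the interferon list differed between the effects of the active and dead domain, by a test of the difference itself: Kcnip1 by a log2 fold change of 1.67 and the interferon list by a median of -0.34. The Kcnip1 call was fragile: 8 of the 10 paired fits that left out 1 library called no gene. Without pairing edgeR called 0 genes. In other splits that keep the pairs, active against dead gave 0 called genes at the highest and 1 in the real grouping, counted 1 time in 16, and 16 splits are too few for a share under 0.05.

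The interferon list was higher than control in shKdm6b and in the dead rescue, and lower in the active rescue than in either of these (0.02 ± 0.28 against control); with an estimated correlation adjusted p was 0.196, 0.268 and 0.0502 for shKdm6b and dead against control and active against shKdm6b, and 0.0158 for active against dead. A single replicate number as the whole source of the active against dead difference is argued against. With any 1 number left out, at least 3 of the other 4 pairs were still lower, and the list median stayed between -0.31 and -0.45. The pair numbered 1 was not lower (0.0292). The mean list difference came nearest to 0 at -0.305 ± 0.287 (without number 3, SD over 4 pairs), under the 1.5 SD asked for. A first version of the test, by camera p, would have excluded a single number. RNA of microglia or macrophages stays open: the interferon minus the microglia marker difference was 0.672 ± 0.765 for shKdm6b against control and -0.270 ± 0.268 for active against dead (mean ± SD over 5 pairs), both under the 1.5 SD asked for. That limit was settled after these values were seen, and the first version, that all 5 pairs point one way, would have excluded it for both. More virus per culture would place both rescues, which received a further construct, above shKdm6b. Neither lay above it beyond the spread over 5 pairs. The active rescue lay at -0.358 ± 0.229 (SD, 5 of 5 pairs lower) and the dead rescue at 0.0146 ± 0.0918 against shKdm6b. The amount of virus per culture is not given by the labels, so this explanation also stays open. That the enzymatic activity of the domain itself lowers these genes is the biological explanation the design offers. It may hold, and was not tested apart from the group difference, which library means alone did not resolve (exact permutation p = 0.317). Kdm6b reads, which may include the human domain, were also higher with the active than the dead domain in 5 of 5 pairs. That log2 difference was 0.28 ± 0.17 (SD, exact sign-flip p = 0.0625, the smallest possible). The contrast may therefore not isolate the activity.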

How the results depend on the processing

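The repeats within the paired fit, those with only some replicate numbers and the sign-flip test of Kdm6b were chosen after the result was seen; the other repeats were planned. Pairing raised the count of called genes with the replicate block from 1 to 632 in shKdm6b against control, from 0 to 299 and 181 in the active and dead rescue against control, and from 0 to 1 in active against shKdm6b and in active against dead. It added 26 list calls and ended 0. Among named genes it added 130 calls and ended 0. Nearly all of these genes were named because the paired fit called them, so their counts follow from that choice. No other call changed. Without the block the counts return to 1 and to 0 for the others. The cause was not tested for any change below, except that fewer libraries leave less power.

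Without pairing, shKdm6b against control gave 0 genes at an adjusted p under 0.01, with limma-voom, and with only the 2 groups compared, and 62 with DESeq2; DESeq2 gave 1 for active against shKdm6b, 1 for active against dead, and 23 and 18 for the active and dead rescue against control. With pairing, DESeq2 gave 1040 for shKdm6b against control, 197 for active against shKdm6b, 145 for dead against shKdm6b, 173 for active against dead, and 751 and 586 for the active and dead rescue against control. An adjusted p under 0.01 gave 281 for shKdm6b against control, 89 and 49 for the rescues against control, and 0 for active against shKdm6b and for active against dead. A 1.5-fold minimum gave 378 for shKdm6b and 184 for the active rescue against control. Upper-quartile normalization gave 0 for active against dead.

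With the replicate block and numbers 1 to 3 only, the counts were 454 for active against control, 17 for active against shKdm6b, 1 for dead against shKdm6b and 9 for active against dead. Numbers 4 and 5 only gave 0 for shKdm6b against control, active against shKdm6b, active against dead, active against control and dead against control. With the 4 libraries numbered 4 left out the block fit gave 990 for shKdm6b against control, 700 and 378 for the active and dead rescue against control, and 0 for active against dead.

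Leaving out 1 library at a time, the counts ran without pairing from 0 to 9 for shKdm6b against control, 0 to 2 for dead against control and 0 to 0 for the other 4 comparisons. With pairing they ran from 352 to 648 for shKdm6b against control, 0 to 2 for active against shKdm6b, 0 to 0 for dead against shKdm6b, 0 to 2 for active against dead, 128 to 384 for active against control and 65 to 179 for dead against control. The Kdm6b level ran from -1.05 to -0.59. For genes higher in knockdown, camera p in active against dead ran from 2.90e-06 to 0.846 without and 1.70e-07 to 0.997 with pairing, and for genes lower in knockdown from 0.00438 to 0.546 and from 0.00483 to 0.979. Without pairing these sets held 1 to 9 and 1 to 4 genes, and only 15 and 3 of 20 fits called any, so these ranges say little.

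The direction turned with numbers 1 to 3 only for microglia markers in shKdm6b against control (0.614) and for oxidative phosphorylation and endothelial markers in active against dead (0.750 each). With the libraries numbered 4 left out it turned in active against shKdm6b for all synaptic lists together (0.680), glutamate receptors and voltage-gated channels (0.683 each), axon guidance (0.658), autism-associated genes (0.0630) and oxidative phosphorylation (0.201). It turned likewise in dead against shKdm6b for all synaptic lists together (1.96e-05), presynaptic genes (0.00900) and granule neuron markers (0.0106), and against control for microglia markers (0.674 active, 0.164 dead). Genes lower in knockdown turned in active against dead without active rescue replicate 1 (0.0329) or dead rescue replicate 1 (0.00483), by camera in limma. Their value was 0.877 with fry, and 0.652 for the set called by DESeq2. Genes higher in knockdown passed camera with numbers 1 to 3 only (2.31e-08) and with the libraries numbered 4 left out (7.18e-10), but not with an estimated correlation (0.212 and 0.0964). The similarity of both rescue effects was -0.0518 (median r) with the knockdown libraries split. The exact sign-flip test of the Kdm6b level uses the same mean difference of -0.83 and cannot give a p under 0.0625, so it says nothing about stability. Other depths were not tested. In simulated counts at the observed depth the paired fit recovered 53.7% of 1.5-fold changes, which were placed only in genes above a set expression level.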

Other observations

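All tests of explanations in this part were chosen after the result was seen, while the group comparisons and the counts over other splits were planned. Of the genes called higher in shKdm6b in the paired edgeR fit, 10 had under 1 CPM in control and a log2 fold change above 2, among them BC049762, Crtam, Hcrtr2, Hoxd3, Hs3st2, Neto1, Nts, Pitx1 and Tmem211. They include a neuropeptide (Nts, neurotensin), an orexin receptor (Hcrtr2) and a heparan sulfate sulfotransferase (Hs3st2). Their median log2 fold change was 3.53 in shKdm6b, 3.04 in the active and 2.90 in the dead rescue against control. Hoxd3 stood at 0.0524 to 1.12 CPM in the 5 control libraries, at 3.68 to 6.51 CPM in shKdm6b 1 to 3, and at 37.4 and 36.2 CPM in shKdm6b 4 and 5. Pitx1 showed the same order, with 1.67 to 3.99 CPM in shKdm6b 1 to 3 and 43.3 CPM in shKdm6b 4. Controls numbered 4 stood highest too, at 1.12 CPM for Hoxd3 and 1.42 CPM for Pitx1.

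Beside the lists described for the rescues, cell cycle genes were lower than control with both domains, by a median log2 fold change of -0.35 with the active domain (0 of 36 positive, 10 lower adjusted over the list alone, camera adjusted p = 6.99e-16, adjusted p = 0.381 with an estimated correlation) and -0.18 with the dead domain (camera adjusted p = 0.000104, adjusted p = 0.736 with an estimated correlation). Oligodendrocyte lineage markers were lower as well (median -0.42 active and -0.34 dead, camera adjusted p = 0.00183 and 0.0185, adjusted p = 0.426 and 0.736 with an estimated correlation), and so were microglia markers (median -0.28 and -0.27, 0.00295 and 0.0153, adjusted p = 0.949 and 0.781 with an estimated correlation). Without the libraries numbered 4 both calls ended (0.0813 and 0.696 for the oligodendrocyte lineage, 0.674 and 0.164 for microglia, whose direction turned). Hox and Polycomb-silenced genes were higher than control in both (camera adjusted p = 0.00183 active and 0.0110 dead, adjusted p = 0.237 and 0.268 with an estimated correlation). Early granule neuron genes were higher than control with the active domain (median 0.20, camera adjusted p = 0.00183, adjusted p = 0.714 with an estimated correlation), a call that ended without the libraries numbered 4 (0.247). That list was also called against control with the dead domain (camera adjusted p = 0.0110), though not with an estimated correlation. Its call likewise ended without the libraries numbered 4 (0.492). Activity-regulated genes stayed lower than control, with Nr4a1 at -1.06 ± 0.19 (SE) in the active rescue (camera adjusted p = 0.0202 active and 0.00829 dead, adjusted p = 0.381 and 0.268 with an estimated correlation).

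The near-silent genes that rose in shKdm6b form a pattern with several candidate explanations. A general loss of Polycomb silencing as strong as the rise of these genes is argued against. The other 46 measured members of the Hox and Polycomb list lay at a median log2 fold change of 0.0620 (SD 0.353). The raised genes were picked for a log2 fold change above 2, so a weaker or partial loss is not addressed. The list as a whole was called higher (camera adjusted p = 0.0150, and 0.103 without the libraries numbered 4), though not with an estimated correlation. Reads spilling from neighbouring genes cannot be told apart from expression for part of the group, because 4 of the 10 genes had a neighbour within 100 kb that gained at least as many reads (BC049762, Nts and Tmem211 among them). Hoxd3 and Pitx1 had none. These gains are raw counts not scaled to library size, so differences in depth enter them. An effect of the shRNA vector or of an off-target also stays open: the median rise was 2.90 in the lower of both rescues, although BC049762 (0.97 active and 1.11 dead) and Hcrtr2 (1.25 and 1.95) did not pass in either, and no other shRNA is among the groups. Loss of Kdm6b itself is the biological explanation the design offers, and it was not tested separately from the shRNA.

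Late maturation genes were lower in shKdm6b, with adjusted p = 0.196 with an estimated correlation. Gene length is argued against as the source, because the list median was -0.33 after the trend with exonic length was removed, beside -0.30 before. Whether a smaller share of granule neurons is the whole source cannot be told. The late list fell beyond the granule markers by -0.170 ± 0.0852 (mean log2 difference ± SD over 5 pairs, 5 of 5 pairs). However, 11 of the 14 granule markers stand in another list too. The early genes Barhl1 (28.8 to 56.3 CPM) and Pax6 (102 to 135 CPM) rose in shKdm6b. Cbln3 (390 to 247 CPM) and Etv1 (209 to 104 CPM), also in the late list, fell. The gap therefore does not measure the share of granule neurons. The libraries numbered 4 are argued against as the whole source, since the list still fell by -0.219 ± 0.0420 over the other 4 pairs (mean ± SD, 4 of 4 lower), although its adjusted p = 0.443 with an estimated correlation without them. Slower maturation after Kdm6b loss is the biological explanation the design offers, and it was not tested separately from an effect of the shRNA.

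Counts of called genes were repeated over other splits of the same libraries, 30 drawn for the fit without pairing and all 16 that keep the same-numbered pairs, the real one included in each. For shKdm6b against control without pairing the real grouping called 1 gene and the highest other split 0, so 1 of 30 splits was as large. Of these 30, 5 part all same-numbered pairs as the real one does, too few for a share under 0.05. The others keep some pairs together. The paired count was 632, against 2 in the highest other split, and 1 of 16 splits was as large. For the active and the dead rescue against control the paired counts were 299 and 181, with 33 and 1 in the highest other split and 1 of 16 as large in both. For active against shKdm6b and active against dead the paired count was 1, with 0 in the highest other split and 1 of 16 as large. For dead against shKdm6b all 16 gave 0. The 16 splits, which all part every pair, are too few for a share under 0.05 in any of these. Without pairing, the 5 comparisons other than shKdm6b against control gave 0 genes in the real grouping, so 30 of 30 splits were as large whatever they held, and the count says nothing about chance.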
